A study of Mus musculus with 3 samples.

How the data were processed

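RNA was sequenced from cultured cells of 3 populations of the mouse mammary carcinoma line JC (JC-WT, JC-P and JC-M3), with 1 polyadenylated-RNA library each. The deposited table gives TPM, a length-scaled abundance per gene, for 55471 features, which the authors made by dividing reads per gene by gene length and scaling each library, per the file headers and column sums. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.9a and featureCounts without a version, with the mouse builds mm10 and GRCm38. The annotation release and the strand setting are not given in the sources used here. Coordinates are those of GRCm38 in GENCODE M21.

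The design foresaw either counts, scaled by trimmed means, or normalized values used as deposited. The table held TPM, so the branch for counts was not used. Each comparison (JC-P over JC-WT, JC-M3 over JC-P and JC-M3 over JC-WT) took the log2 ratio of TPM + 0.5 among the 14527 features with a mean of at least 1 TPM over the 3 libraries. A gene was called higher or lower where the ratio was at least 2-fold. With 1 library per group there was no replicate check, no significance test was run and no p-value was computed across genes. These choices, the gene lists and the rule for named genes were fixed before the data were examined.

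Multiplying TPM by the merged exon length of GENCODE M21, known for 55144 features, gave whole multiples of a fixed step in each library. Dividing by that step recovered a whole read number, within 0.01 of a read, for 98.4% of expressed genes in JC-WT, 98.5% in JC-P and 98.5% in JC-M3. From these reads came exact conditional (Clopper-Pearson) 95% intervals of each ratio and a floor of 3 reads per library for genes with 0 reads. A fold against that floor leaves out the counting error of the other library, so the lower limit of the interval lies below it. Duplicate reads are not independent molecules, so intervals and floors cover counting error only. For the named genes and list members, the share of 50-base windows of its transcripts that also occur in other genes was computed as a check for paralogs.

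The median log2 ratio of each of 45 fixed gene lists was placed among 10000 random lists of the same size matched on mean expression in 10 bins. The percentile describes these libraries and is not a p-value. Of 45 lists, 43 had a measured member, and 43 of their 129 percentiles lay outside the central 95%, where 6.45 would for lists of independently drawn genes. Genes within a list can vary together, so the excess is not a measure of chance. The lists overlap, as with Acta2, which is both a mesenchymal and a basal gene. The genes named were the 12 highest and 12 lowest ratios per comparison among genes with a mean of at least 10 TPM and without predicted or clone names, the 2 highest and 2 lowest members of each list, the ATP synthasome members, measured markers of other cell types, and the 5 largest steps each way across both steps. The most abundant transcript was also eligible. Overlaps between comparisons were set beside the product expected of independent lists and beside 100 Poisson draws of unchanged libraries. Medians per chromosome used protein-coding genes and were set beside 10000 random draws of as many genes, a step added after the data were seen.

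The alternatives run differed by kind of result. Counts of genes and their overlaps were recomputed with other scalings, pseudocounts, expression filters and thresholds, and with features left out. List medians were recomputed with other scalings, pseudocounts and expression filters and with chromosome medians subtracted. Named genes were recomputed with other scalings and pseudocounts and with chromosome medians subtracted. The scripts were tested on simulated data with 200 changed genes among 14491. Genes changed 1.5-fold, 2-fold, 3-fold and 4-fold were called in 4%, 36%, 94% and 94% of cases for JC-P over JC-WT, in 8%, 36%, 94% and 94% for JC-M3 over JC-P and in 4%, 36%, 98% and 96% for JC-M3 over JC-WT. Unchanged genes were called in 2.54%, 2.29% and 2.41% of cases. The true ratio lay inside the interval for 96.7% of 20570, 96.5% of 20635 and 96.7% of 20605 genes. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.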

Results

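RNA sequencing of polyadenylated RNA was available for 3 cultured populations of JC cells, a mouse mammary carcinoma line with epithelial-like cells, with 1 library per population. JC-WT carries the label WT. Per the labels' protocols, JC-P came from mammary fat pad tumours taken at day 14, and JC-M3 from lung metastases after 3 rounds of tail vein injection of cells derived from JC-P, with isolation after 28 days. The treatment label of JC-P, however, reads metastasis, as does that of JC-M3, so its origin is taken from the protocol alone. There were no replicates, so each ratio describes a pair of libraries and none was tested for significance. The reads assigned to genes, recovered from the deposited values, numbered 18088800 in JC-WT, 22124700 in JC-P and 23378000 in JC-M3. A gene was measured where its mean over the 3 libraries reached 1 TPM, which held for 14527 of 55471 features. Ratios are log2 values of TPM + 0.5, a scale that understates the differences of low genes. The intervals beside them are 95% exact counting intervals of the plain TPM ratio, so a log2 value of a low gene can lie outside its interval. They cover counting error only, without variation between cultures. The most abundant transcript in every library was mt-Co1, a mitochondrially encoded subunit of cytochrome c oxidase, at 16638 TPM in JC-WT, 23037 TPM in JC-P and 17692 TPM in JC-M3. Mitochondrial transcripts took 4.51%, 5.46% and 5.22% of the TPM in the same order.

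The series title names the ATP synthasome, the assembly of ATP synthase with its phosphate and adenine nucleotide carriers, so its 22 measured genes were compared first. The theme may have been chosen on these samples, in which case the list is not independent evidence. Transcript levels of the ATP synthasome differed little between the 3 populations. The median log2 ratio was -0.04 for JC-P over JC-WT, -0.05 for JC-M3 over JC-P and -0.15 for JC-M3 over JC-WT, at percentiles 58.8, 19.95 and 10.5 of 10000 random lists matched on expression. Of the 22 genes, 21 lay within 2-fold for JC-P over JC-WT, all 22 for JC-M3 over JC-P and 21 for JC-M3 over JC-WT. The exception in both cases was mt-Atp8, a mitochondrially encoded subunit, at 42.9 TPM in JC-WT, 97.7 TPM in JC-P and 95.7 TPM in JC-M3. Its log2 ratio for JC-P over JC-WT was 1.18 (0.70 to 1.70), from 47 and 131 reads. Atp5f1b, the catalytic beta subunit, stood at 1394, 1366 and 1505 TPM in JC-WT, JC-P and JC-M3. The adenine nucleotide carrier Slc25a5 stood at 1035, 882 and 755 TPM, and the phosphate carrier Slc25a3 at 186, 214 and 254 TPM. The lowest ratio of JC-M3 over JC-WT was that of Atp5f1e, the epsilon subunit, at -0.70 (-0.92 to -0.50). Many of these small differences exceeded counting error, with intervals that left out no change for 16, 16 and 19 of the 22 genes in the 3 comparisons. Of the 50-base windows of mt-Atp6 transcripts, 99.5% also occurred in transcripts of other genes, so its level (243, 330.0 and 267 TPM) is uncertain. For mt-Atp8 that share was 0%, but the check covers annotated transcripts only. In JC-WT mt-Atp8 stood far below mt-Nd1 (7861 TPM), so the level of mt-Atp8 may be uncertain as well.

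**Figure D1:**
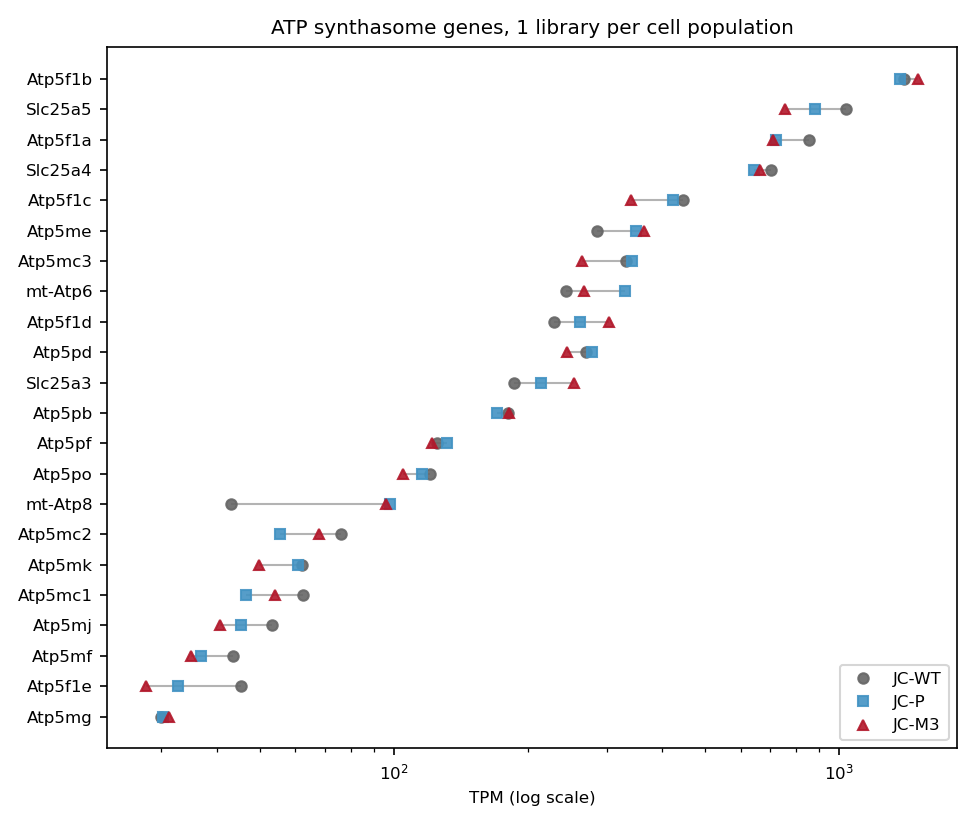
TPM on a log axis for the 22 measured ATP synthasome genes, with 1 point per library (JC-WT circles, JC-P squares, JC-M3 triangles) and a grey line over the range of each gene. The range of mt-Atp8, from 42.9 to 97.7 TPM, is the widest, and Atp5f1b is the most abundant member at 1366 to 1505 TPM.

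Lists of nuclear energy metabolism genes had median ratios slightly below 0 for JC-M3 over JC-WT, whereas the 13 mitochondrially encoded protein genes had a median of 0.22. The latter also lay inside the central 95% of random lists, at percentile 97.445, with 3 of 13 genes below 0. For JC-M3 over JC-WT the median log2 ratio was -0.14 for 36 nuclear genes of respiratory complex I, -0.25 for 14 of complexes II and III, -0.18 for 13 of complex IV, -0.12 for 23 genes of the tricarboxylic acid cycle, -0.09 for 21 glycolysis genes and -0.04 for 21 fatty acid oxidation genes. All 6 medians lay within the central 95% of random lists, at percentiles from 3.54 to 42.7. With chromosome medians subtracted, the median of complexes II and III turned to 0.0346 and that of glycolysis was -0.28. The 75 mitochondrial ribosome genes had a similar median of -0.18, which lay outside the central 95% at percentile 0.33, with 56 below 0 and 1 at least 2-fold lower. Single members stood apart. Ldhb, a lactate dehydrogenase subunit, had 0 reads in JC-P and 56 reads in JC-M3. It was 17.9-fold higher against a floor of 3 reads per library, and the lower limit of its interval lies below that fold. Uqcr11, a complex III subunit, stood at 253 TPM in JC-WT, 123 TPM in JC-P and 442 TPM in JC-M3. The succinate dehydrogenase subunit Sdha was at 261, 221 and 137 TPM. Genes of cristae and mitochondrial dynamics had a median of -0.11 for JC-M3 over JC-WT, with the fission gene Fis1 at 52.9, 142 and 126 TPM and the fusion gene Mfn1 at 32.3, 44.9 and 68.5 TPM. The 12 measured phosphagen and adenylate kinases had a median of -0.41 for JC-M3 over JC-P (percentile 0.43; -0.26 with chromosome medians subtracted), with the brain creatine kinase Ckb at 7.83 TPM in JC-P and 2.16 TPM in JC-M3 and the nucleoside diphosphate kinase gene Nme4 at 22.7 and 7.83 TPM.

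The comparison of JC-P with JC-WT asks what differed in cells that had grown in the mammary fat pad. Several interferon-stimulated and matrix genes were at least 2-fold higher in JC-P. The lists of antigen presentation genes on one side, and of cell cycle genes and TGF-beta targets on the other, had shifted medians with few or no members past 2-fold. Of 40 measured interferon-stimulated genes, 38 had a log2 ratio above 0, 12 were at least 2-fold higher and 0 at least 2-fold lower. Ifi44l stood at 12.6 TPM in JC-WT and 75.5 TPM in JC-P, a log2 ratio of 2.54 (2.27 to 2.91). The median of the list was 0.89, above all 10000 random lists. In all, 692 features were at least 2-fold higher in JC-P and 339 at least 2-fold lower.

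The highest ratios of JC-P over JC-WT belonged to H19, an imprinted long noncoding RNA (1.36 and 24.1 TPM, log2 3.72, 3.47 to 4.92), and to the collagen genes Col3a1 (3.99 and 46.0 TPM, log2 3.37, 3.33 to 3.74) and Col6a3 (5.23 and 57.6 TPM, log2 3.34, 3.30 to 3.62). H19 lies on chromosome 7 from 142575529 to 142578143 and Col3a1 on chromosome 1 from 45311538 to 45349706 (GRCm38). The matrix proteoglycan gene Dcn followed with 1.24 and 14.0 TPM, the focal adhesion gene Tns1 with 1.40 and 11.9 TPM, Rgcc with 2.44 and 17.2 TPM and the chemokine gene Ccl7 with 4.19 and 27.2 TPM. Bglap2, of the osteocalcin family, stood at 45.9 and 233 TPM, but 88.2% of its 50-base windows occur in other genes and its level is uncertain. Mir1957a, Snord138 and Mir7027 also ranked among the 12 highest, each with 1 read in JC-WT, and their ratios had intervals of 0.22 to 8.47, -0.19 to 8.18 and -0.45 to 8.01. The lowest ratio was that of Lcn2, encoding a secreted siderophore-binding lipocalin, with 152 TPM in JC-WT and 11.2 TPM in JC-P (log2 -3.71, -3.98 to -3.55). It was followed by Acta2, the smooth muscle actin gene (16.5 and 2.22 TPM, log2 -2.64, -3.48 to -2.35), Prxl2a (104 and 16.3 TPM) and the organic anion transporter gene Slco4a1 (99.9 and 20.2 TPM). Also lower were the adhesion molecule gene Mcam (9.68 and 2.00 TPM), Cd34 (90.6 and 26.5 TPM), the zinc receptor gene Gpr39 (63.8 and 18.6 TPM), the natriuretic peptide gene Nppb (236 and 87 reads) and the granulocyte growth factor gene Csf3 (44.3 and 13.4 TPM). Actg2, the enteric smooth muscle actin gene, had 12 reads in JC-WT and 1 in JC-P, a ratio with an interval of -9.29 to -1.12. mt-Tm and Snord35a rested on 2 reads each in JC-P, with intervals of -5.22 to 0.61 that include no change.

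By gene list, the medians of JC-P over JC-WT lay outside the central 95% of random lists for 16 of 43 lists with a measured member. Besides the interferon list, the 21 MHC class I and antigen processing genes had a median of 0.54, also above all random lists, with 20 above 0 and 2 at least 2-fold higher, among them the immunoproteasome gene Psmb9 at 7.69 and 18.5 TPM. The 27 chemokines and cytokines were divided, with a median of 0.35, 16 above 0 and 11 below, 6 at least 2-fold higher, among them Ccl2 at 119 and 435 TPM, and 1 lower. With no filter on the mean their median was 0.16. Hypoxia response genes had a median of 0.32 over 22 genes, with the vasoactive peptide gene Adm at 2.88 and 12.9 TPM and Bnip3 at 37.7 and 71.8 TPM. All 13 mitochondrially encoded protein genes were above 0, with a median of 0.36. Several of them are uncertain because much of their sequence occurs in other genes, among them mt-Co1 (51.1% of windows), mt-Co3 (99.9%) and mt-Nd3 (98.0%). Those with little shared sequence ranged from mt-Nd1 and mt-Nd2, with log2 ratios of 0.06 and 0.09, to mt-Nd6 and mt-Atp8, with 0.74 and 1.18. The ratio of mt-Atp8 may be uncertain too, since in JC-WT it stood at 42.9 TPM against 7861 TPM for mt-Nd1. The 28 collagens and matrix genes had a median of 0.25, with 5 at least 2-fold higher and 1 lower, the fibulin gene Fbln2 (20.4 and 6.90 TPM). Cell cycle and mitosis genes had a median of -0.38, below all random lists, with 27 of 32 below 0 and none at least 2-fold lower. Rrm2, the ribonucleotide reductase subunit, was at 313 TPM in JC-WT and 171 TPM in JC-P. TGF-beta targets and ligands had a median of -0.37, likewise below all random lists, with 16 of 20 below 0 and 3 at least 2-fold lower, among them the BMP antagonist Grem1 at 219 and 73.5 TPM and Ltbp2 at 35.9 and 14.4 TPM. With a mean of at least 10 TPM the median was -0.66. Lists with lower medians also included 75 mitochondrial ribosome genes (-0.20) and 13 mitochondrial biogenesis regulators (-0.32). Further ones were 16 immediate early and dissociation genes (-0.30) and 15 stemness and Wnt genes (-0.28). The 11 measured of 32 epithelial genes had a median of -0.52, and the 7 measured of 16 basal and myoepithelial mammary genes -0.39. With no filter on the mean the last 2 were -0.15 and -0.18, and epithelial genes with a mean of at least 10 TPM had -0.0915.

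Some markers of other cell types were higher in JC-P, and others were level or lower. The 8 measured fibroblast markers had a median of 0.55 for JC-P over JC-WT, or 0.33 with no filter on the mean. The highest of them, Col3a1 and Dcn, are matrix genes already named above, so this median is not separate from the matrix genes. Cdh5, the endothelial cadherin gene, had 2 reads in JC-WT, 490 reads in JC-P and 3 reads in JC-M3 (log2 4.95 for JC-P over JC-WT, 5.78 to 10.69), and the endothelial gene Plvap was at 7.60, 17.8 and 2.71 TPM. Of 14 endothelial markers only 4 were measured, and the rest stayed below a mean of 1 TPM. Besides Cdh5 and Plvap, the measured ones were level, with Eng at 265 TPM in both libraries and Egfl7 at 4.06 and 3.31 TPM. The myeloid markers Cd68 (11.9 and 6.78 TPM), Cd14 (55.2 and 42.3 TPM) and Itgax (2.06 and 0.73 TPM) were lower in JC-P. Poisson draws of unchanged libraries at these depths gave means of 178 features 2-fold higher and 176 lower.

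**Figure D2:**
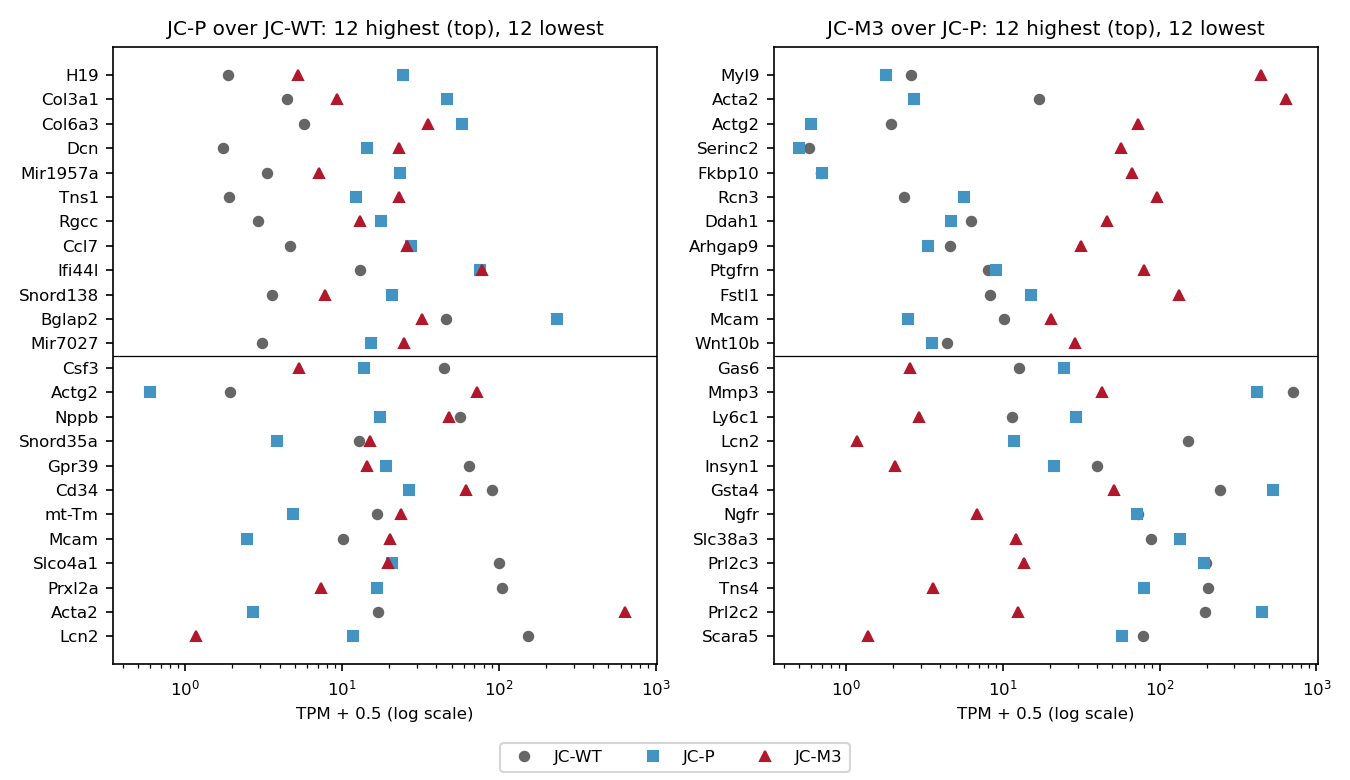
TPM + 0.5 on a log axis for the 12 genes with the highest and the 12 with the lowest ratio among genes with a mean of at least 10 TPM, for JC-P over JC-WT (left) and JC-M3 over JC-P (right), with 1 point per library. On the right, Myl9 and Acta2 stand at 444 and 642 TPM in JC-M3 and at 1.31 and 2.22 TPM in JC-P.

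The comparison of JC-M3 with JC-P asks what differed after repeated passage through the lung. The smooth muscle genes Myl9, Acta2 and Actg2 were far higher in JC-M3. Of the fixed lists, TGF-beta targets and cell cycle genes had raised medians. Both lists had medians below 0 for JC-P over JC-WT (-0.37 and -0.38), and for JC-M3 over JC-WT the cell cycle median was 0.05. Epithelial genes were divided, with more at least 2-fold lower than higher. Myl9, the smooth muscle myosin light chain gene, stood at 1.31 TPM in JC-P and 444 TPM in JC-M3, a log2 ratio of 7.94 (7.53 to 9.47). Acta2 stood at 2.22 and 642 TPM, a log2 ratio of 7.88 (7.68 to 8.73). Altogether 555 features were at least 2-fold higher in JC-M3 and 781 at least 2-fold lower.

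Myl9 lies on chromosome 2 from 156775420 to 156781658 and Acta2 on chromosome 19 from 34241090 to 34255590, so the pair is not adjacent. Actg2 had 1 read in JC-P and 775 in JC-M3 (72.6 TPM), with an interval of 7.05 to 14.84. Serinc2, which encodes a serine incorporator family protein, had 0 reads in JC-P and 56.3 TPM in JC-M3. It was 286-fold higher against the floor of 3 reads, and the lower limit of its log2 interval was 7.86. Genes of collagen folding in the endoplasmic reticulum followed, Fkbp10 with 0.21 and 66.4 TPM and the calcium-binding Rcn3 with 5.14 and 96.3 TPM. The remaining genes among the 12 highest were Ddah1 (4.20 and 45.7 TPM), Arhgap9 (2.81 and 30.9 TPM), Ptgfrn (8.54 and 79.3 TPM), the follistatin-like gene Fstl1 (14.6 and 132 TPM), Mcam (2.00 and 19.8 TPM) and the Wnt ligand gene Wnt10b (3.04 and 28.2 TPM). The lowest ratio was that of Scara5, a ferritin receptor gene, with 57.4 TPM in JC-P and 0.89 TPM in JC-M3 (log2 -5.39, -6.53 to -5.55). The prolactin family genes Prl2c2 (3224 and 90 reads) and Prl2c3 (192 and 13.2 TPM) were lower too, but 83.3% and 60.0% of their windows are shared with other genes, so how reads divide between them is uncertain. Lower genes with mostly unshared sequence were the tensin gene Tns4 (79.5 and 3.07 TPM), the amino acid transporter gene Slc38a3 (135 and 11.6 TPM), the neurotrophin receptor gene Ngfr (71.5 and 6.39 TPM), the glutathione transferase gene Gsta4 (525 and 50.7 TPM), Insyn1 (20.6 and 1.56 TPM), Lcn2 (11.2 and 0.67 TPM), the stromelysin gene Mmp3 (414 and 42.5 TPM) and Gas6, a ligand of TAM receptors (23.9 and 2.06 TPM). Ly6c1 was at 28.7 and 2.43 TPM with 32.8% of its windows shared.

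Of the 43 lists, 12 had medians of JC-M3 over JC-P outside the central 95% of random lists. TGF-beta targets and ligands had a median of 0.86, above all random lists, with 9 of 20 at least 2-fold higher and 2 lower. Ccn1, a matricellular gene, stood at 89.4 and 543 TPM and Ltbp2 at 14.4 and 88.9 TPM, while Id1 was at 111 and 43.6 TPM and Tgfbi at 4.12 and 1.58 TPM. Cell cycle and mitosis genes had a median of 0.40, above all random lists, with 27 of 32 above 0 and Cdc20 at 161 and 400.0 TPM. Immediate early and dissociation genes, a list included as a quality check, had a median of 0.42, with Junb at 72.6 and 147 TPM. Their median for JC-P over JC-WT was -0.30, so a difference in the handling of the JC-P culture was not separated from these shifts. Of 32 epithelial genes, 11 were measured, and their median was -1.17, below all random lists. Among the 11, 6 were at least 2-fold lower, 2 higher and 5 above 0, so this median lies at the edge of a divided list. It depends on the settings, at -0.49 with pseudocount 2, -1.42 with a mean of at least 10 TPM and -0.00186 with no filter on the mean, which adds low genes. The desmosomal genes Pkp1 (8.57 and 1.68 TPM) and Jup (26.7 and 7.09 TPM) had the lowest ratios. The 20 mesenchymal genes had a median of 0.23, at percentile 98.3, and 0.12 with no filter on the mean. Collagens and matrix genes had a median of 0.27, with 6 at least 2-fold higher, 2 lower and 20 within 2-fold. Col1a1 stood at 261 TPM in JC-P and 949 TPM in JC-M3, whereas its partner chain Col1a2 stood at 0.66 and 4.40 TPM, and Col3a1 was at 46.0 and 8.76 TPM. Hypoxia response genes had a median of -0.22 (-0.34 with a mean of at least 10 TPM), with the carbonic anhydrase gene Car9 at 1031 and 316 reads. Cholesterol and fatty acid synthesis genes had a median of -0.19. The interferon list was slightly lower, with a median of -0.17 at percentile 0.25, 38 of 40 genes within 2-fold and Mx1 at 106 and 51.6 TPM. The 76 cytosolic ribosomal protein genes had a median of 0.15.

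The 8 fibroblast markers went both ways, with Col1a1 and Col1a2 higher and Col3a1, Pdgfra (47.6 and 20.1 TPM) and Dpt (24 and 3 reads, interval -5.44 to -1.34) lower. The 4 measured endothelial markers had a median of -1.40 for JC-M3 over JC-P, at percentile 0.05, with Cdh5 and Plvap at least 2-fold lower. The Endothelial markers median log2 ratio, JC-M3 over JC-P, turned to 0.0443 with a mean of at least 10 TPM, where Eng alone was left, and was -0.0201 with no filter on the mean. Tagln, another smooth muscle gene, stood at 0.84 TPM in JC-P and 2.57 TPM in JC-M3, far below Acta2. Of the 3 measured muscle markers, Tnnt3 was at 13.4 and 3.96 TPM, Des at 5.59 and 6.48 TPM and Myh1 at 2.66 and 2.06 TPM. The 2 measured alveolar and airway markers were level, with Abca3 at 35.5 and 31.9 TPM and Ager at 2.91 and 2.52 TPM. Unchanged Poisson libraries gave means of 154 features higher and 148 lower.

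**Figure D3:**
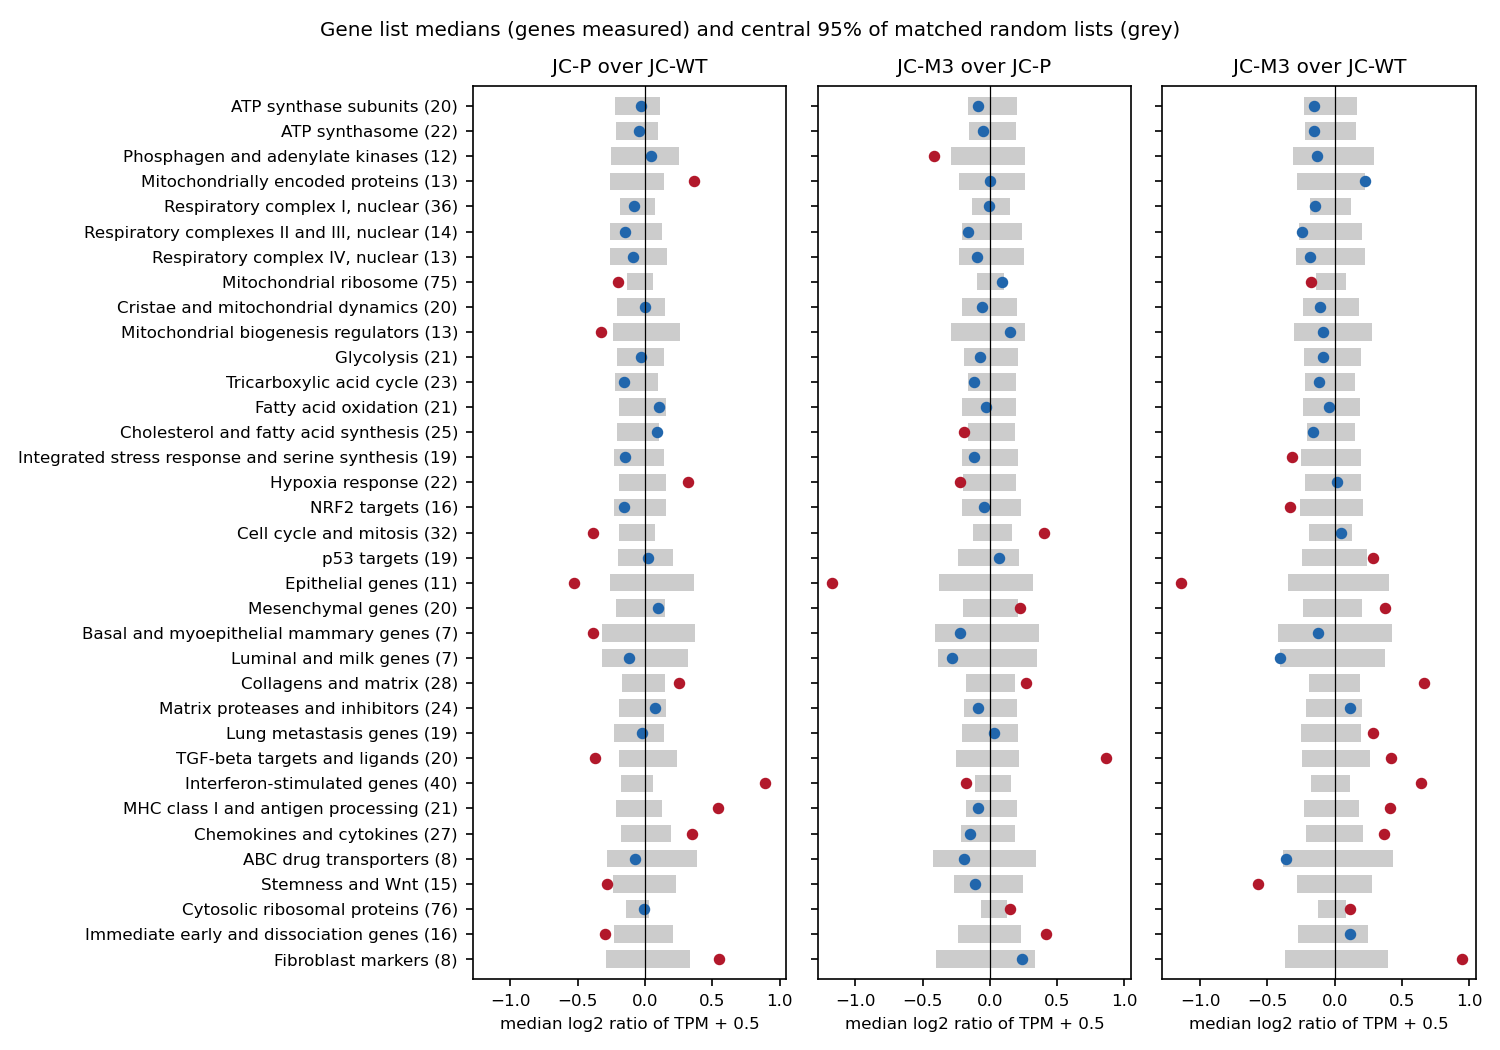
Median log2 ratio (x axis) of each fixed gene list with at least 7 measured genes, in the 3 comparisons, with the number of measured genes in brackets. Grey bars span the central 95% of 10000 matched random lists and red points lie outside it; the interferon-stimulated median of 0.89 for JC-P over JC-WT and the epithelial median of -1.17 for JC-M3 over JC-P are among those farthest from 0.

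The comparison of JC-M3 with JC-WT spans both steps of selection. The medians of the matrix, interferon-stimulated and cytokine lists were above 0, and those of the epithelial, stemness and Wnt, and NRF2 target lists below 0. Myl9 (2.08 and 444 TPM, log2 7.43, 6.96 to 8.65), Serinc2 (1 read and 895 reads, interval 6.97 to 14.76), Fkbp10 (3 reads and 1338 reads, interval 6.90 to 10.73) and Rcn3 (1.84 and 96.3 TPM) had the highest ratios. Lcn2 had the lowest, with 152 TPM in JC-WT and 0.67 TPM in JC-M3 (log2 -7.03, -8.79 to -7.03). There were 892 features at least 2-fold higher in JC-M3 and 766 at least 2-fold lower.

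Further genes among the 12 highest of JC-M3 over JC-WT were Acta2 (16.5 and 642 TPM), Actg2 (1.44 and 72.6 TPM), Fstl1 (7.77 and 132 TPM), Dcn (1.24 and 22.5 TPM), Tns1 (1.40 and 22.5 TPM), Ptgfrn (7.50 and 79.3 TPM), the collagen gene Col5a3 (2.22 and 22.6 TPM) and the BMP antagonist gene Nbl1 (9.71 and 82.2 TPM). Among the 12 lowest, Tns4 was at 202 and 3.07 TPM, Scara5 at 77.9 and 0.89 TPM, Insyn1 at 39.5 and 1.56 TPM, Mmp3 at 708 and 42.5 TPM, the tetraspanin gene Cd53 at 34.0 and 1.67 TPM, the neuronal pentraxin gene Nptx1 at 70.7 and 4.39 TPM, Prxl2a at 104 and 6.82 TPM, Lgi2 at 33.3 and 2.08 TPM and Havcr2, the gene of an immune checkpoint receptor, at 29.7 and 1.93 TPM. Prl2c2 and Prl2c3 completed the 12, with the shared sequence given above. For 15 of the 43 lists the median lay outside the central 95% of random lists. Collagens and matrix genes had a median of 0.66 with 11 of 28 at least 2-fold higher and 3 lower. The 8 fibroblast markers had a median of 0.95 at percentile 99.99, with 4 at least 2-fold higher and 1 lower, and a median of 0.44 with no filter on the mean. Interferon-stimulated genes had a median of 0.64 with 9 of 40 higher and 1 lower. The chemokine Cxcl10 stood at 32.8 TPM in JC-WT, 79.7 TPM in JC-P and 171 TPM in JC-M3, and Ifi27 at 567, 295 and 152 TPM. MHC class I and antigen processing genes had a median of 0.41, chemokines and cytokines 0.36 (7 at least 2-fold higher and 4 lower), TGF-beta targets 0.42, mesenchymal genes 0.37, p53 targets 0.29 and lung metastasis genes 0.28, with Ptgs2, the cyclooxygenase-2 gene, at 210 and 825 TPM. Lower medians were those of epithelial genes (-1.14), stemness and Wnt genes (-0.57, with 4 of 15 at least 2-fold lower), NRF2 targets (-0.33, with 3 of 16 lower) and integrated stress response and serine synthesis genes (-0.32), with Wnt7b at 1711 and 385 reads and the pseudokinase gene Trib3 at 98.0 and 41.1 TPM. The Wnt ligand gene Wnt10b went the other way, at 3.89 TPM in JC-WT and 28.2 TPM in JC-M3. The epithelial median was -0.16 with no filter on the mean, and that of stemness and Wnt genes -0.36 with chromosome medians subtracted. With a mean of at least 10 TPM, TGF-beta targets had 0.14, mesenchymal genes 0.25 and chemokines and cytokines 0.60. Medians of luminal and milk genes (-0.40), ABC drug transporters (-0.36), matrix proteases and inhibitors (0.11) and ATP synthase subunits (-0.15) lay inside the central 95%. So did those of cell cycle and mitosis genes (0.05), hypoxia response genes (0.02) and immediate early genes (0.12), whose shifts in both steps share the single JC-P library. Unchanged Poisson libraries gave means of 177 features higher and 174 lower.

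Across the steps, 46 features were at least 2-fold higher in JC-P than in JC-WT and again in JC-M3 than in JC-P, and 31 were lower in both. Afp, the fetal serum protein gene, went from 0.22 to 3.98 and 23.4 TPM, and the osteoprotegerin gene Tnfrsf11b from 0 reads to 1.57 and 8.38 TPM. Cacng7 (0 reads, 2.93 and 15.3 TPM), Defb25 (0 reads, 2.08 and 17.4 TPM) and Mir762 (0, 1 and 4 reads) also ranked among the 5 largest steps upward. The 5 largest downward were Lcn2, the Notch ligand gene Dll4 (13.8, 2.33 and 0.23 TPM), Ripply1 (9.65, 2.25 and 0.18 TPM), Id4 (14.3, 3.95 and 0.49 TPM) and Itprid1 (14.8, 3.48 and 0.89 TPM). Independent lists of these sizes would share 26.4 features upward and 18.2 downward, and unchanged Poisson libraries, which share JC-P, gave 7.82 and 8.86. The Poisson draws hold counting error only, without variation between cultures. They also called fewer features, with means of 178 higher and 176 lower in the first step and 154 and 148 in the second. Their overlaps thus come from smaller lists than those observed and are not a measure of chance for them. More features went one way and back, with 189 higher in JC-P and then lower in JC-M3, against 37.2 for independent lists and 40.6 in Poisson draws, and 123 lower and then higher, against 12.95 and 86.5. Over the shared JC-WT library, 356 features were higher in both JC-P and JC-M3 (42.5 for independent lists, 106 in Poisson draws) and 156 lower in both (17.9 and 59.5). Where features went one way and back, or were compared over JC-WT, part of the excess may come from the shared library, which cannot be split. With a mean of at least 10 TPM, the genes higher in both steps numbered 6 and the genes lower in both steps 9, and with pseudocount 0.1 they numbered 81 and 51, so these counts rest mostly on low genes.

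Median ratios also differed between chromosomes, a comparison chosen after the data were seen. Over 11375 protein-coding genes, those on chromosome 13 had a median log2 ratio of -0.52 for JC-M3 over JC-P, with 87.0% of its 437 genes below the median of all genes and random draws of as many genes ranging from -0.10 to 0.08. Its lowest window of genes, from 86044816 to 98274754, had a median of -0.84. Chromosome 14 (-0.26) and chromosome 2 (-0.23) were also lower, as was the X chromosome (-0.15). The medians of chromosomes 3 (0.25), 15 (0.24), 10 (0.22) and 4 (0.12) were higher. A chromosome median need not hold along its length. On chromosome 10 the windows up to position 77515785 lay between 0.35 and 0.52, and those beyond it between -0.10 and 0.18. The medians of 7 of 20 chromosomes for JC-P over JC-WT, 8 for JC-M3 over JC-P and 9 for JC-M3 over JC-WT lay outside all random draws. For JC-M3 over JC-WT, chromosome 13 (-0.44) and chromosome 10 (0.41) lay farthest from 0. For JC-P over JC-WT the highest median was that of the X chromosome (0.24). On chromosome 2 the windows from position 84669215 to its end lay between -0.64 and -0.33 for JC-M3 over JC-WT. The low genes Prl2c2 and Prl2c3 lie on chromosome 13, and Scara5 on chromosome 14. Their log2 ratios for JC-M3 over JC-P (-5.17, -3.81 and -5.39) lay far below the medians of those chromosomes.

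**Figure D4:**
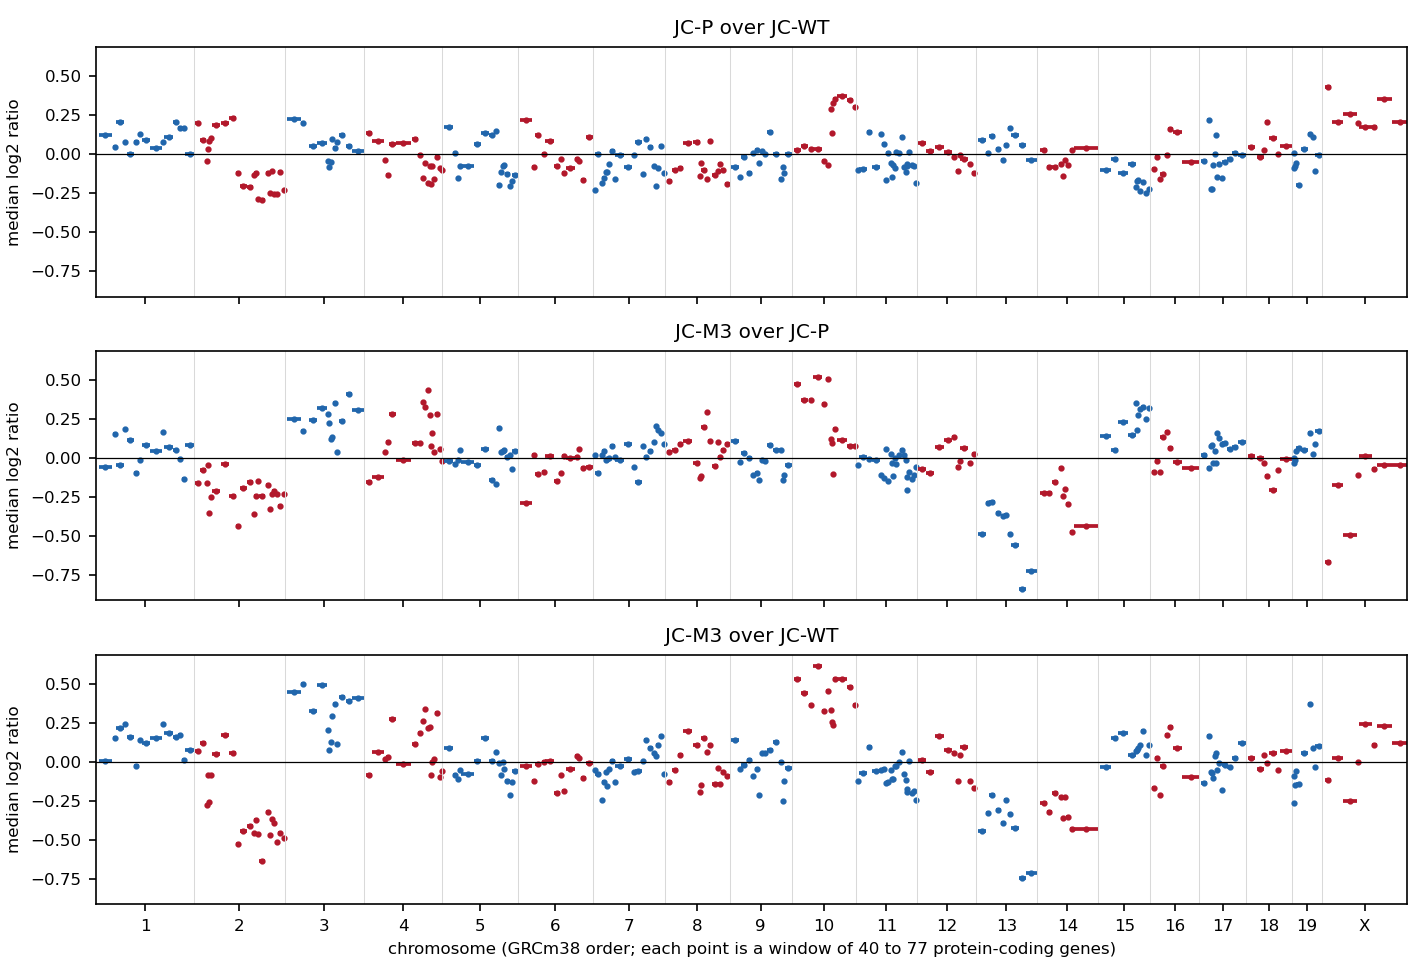
Median log2 ratio (y axis) in consecutive windows of 40 to 77 protein-coding genes along the chromosomes (x axis), for the 3 comparisons. For JC-M3 over JC-P the chromosome 13 windows lie from -0.84 to -0.28, below 0 along the whole chromosome.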

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

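The alternatives with a counting interval, protein-coding genes, chromosome medians subtracted and members with little shared sequence were chosen after seeing the data. Rescaling by the median ratio or the upper quartile and subtracting chromosome medians kept each count of genes within 1.5 times its main value. The ATP synthasome medians held under every alternative run for them. Their percentiles held with random lists not matched on expression. Under other settings, the ATP synthasome percentiles entered only a count of lists outside the central 95%. Over all alternatives, 843 values of list medians held, 53 moved and 1 that had lain outside the central 95% of random lists changed sign. Medians inside the central 95% that moved across 0 were those of complexes II and III, cristae and dynamics, fatty acid oxidation, p53 targets, basal genes, matrix proteases, and alveolar and airway markers. Of the values of named genes, 294 held and 66 moved toward 0, 48 of them with pseudocount 2 and 18 with chromosome medians subtracted. No paired analysis was possible because each group has 1 library without replicate numbers. Stricter filters and thresholds test or pass fewer genes by construction; for the pseudocounts the cause was not tested. Depth limits genes with few reads, for which counting error alone can exceed 2-fold.

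For genes higher, JC-P over JC-WT, the number was 361 with pseudocount 2, 1288 with no filter on the mean, 156 with a mean of at least 10 TPM, 181 with a 4-fold threshold, 353 without predicted or clone names, 417 where the counting interval must leave out no change and 273 for protein-coding genes only. For genes lower, JC-P over JC-WT, the same settings gave 173, 647, 63, 82, 180, 186 and 138.

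For genes higher, JC-M3 over JC-P, pseudocount 2 gave 328, no filter 1024, a mean of at least 10 TPM 154, the 4-fold threshold 137 and protein-coding genes 316. For genes lower, JC-M3 over JC-P, these gave 443, 1288, 269, 178 and 454, and leaving out predicted names 507.

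For genes higher, JC-M3 over JC-WT, pseudocount 2 gave 522, no filter 1544, a mean of at least 10 TPM 247, the 4-fold threshold 254, leaving out predicted names 553 and protein-coding genes 475. For genes lower, JC-M3 over JC-WT, pseudocount 2 gave 471, a mean of at least 10 TPM 293, the 4-fold threshold 190 and protein-coding genes 485.

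Among genes higher in both steps, pseudocount 0.1 gave 81, pseudocount 2 gave 9, a mean of at least 10 TPM 6 and the 4-fold threshold 4. Among genes lower in both steps, these gave 51, 9, 9 and 1. For genes higher then lower, pseudocount 2 gave 102, no filter on the mean 501, a mean of at least 10 TPM 38, the 4-fold threshold 41 and leaving out predicted names 100. For genes lower then higher, pseudocount 2 gave 41, a mean of at least 10 TPM 22, the 4-fold threshold 31 and leaving out predicted names 65. For genes higher in JC-P and JC-M3 over JC-WT, these gave 140, 66, 93 and 190. For genes lower in JC-P and JC-M3 over JC-WT, they gave 78, 24, 28 and 89, and no filter on the mean 358.

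With no filter on the mean, which adds genes whose ratios the pseudocount draws to 0, the list medians that moved were epithelial genes -0.15, basal and myoepithelial mammary genes -0.18, chemokines and cytokines 0.16, fibroblast markers 0.33 and endothelial markers 0.00199 for JC-P over JC-WT. For JC-M3 over JC-P they were NRF2 targets -0.17, epithelial genes -0.00186, mesenchymal genes 0.12, luminal and milk genes -0.0754, chemokines and cytokines -0.00244, neutrophil markers 0.21 and endothelial markers -0.0201. For JC-M3 over JC-WT they were epithelial genes -0.16, collagens and matrix 0.56, matrix proteases and inhibitors -0.0164, ABC drug transporters -0.14, stemness and Wnt -0.39 and fibroblast markers 0.44.

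With a mean of at least 10 TPM, which leaves fewer genes, they were p53 targets -0.25, epithelial genes -0.0915, matrix proteases and inhibitors -0.10, TGF-beta targets and ligands -0.66, chemokines and cytokines 0.20, fibroblast markers 0.73, endothelial markers 0.00199 and alveolar and airway epithelial markers -0.10 for JC-P over JC-WT. For JC-M3 over JC-P they were cristae and mitochondrial dynamics 0.0688, hypoxia response -0.34, p53 targets 0.24, epithelial genes -1.42, matrix proteases and inhibitors -0.26, TGF-beta targets and ligands 0.71 and stemness and Wnt -0.36. For JC-M3 over JC-WT they were glycolysis -0.31, epithelial genes -1.37, mesenchymal genes 0.25, basal and myoepithelial mammary genes -0.61, matrix proteases and inhibitors -0.0350, TGF-beta targets and ligands 0.14, chemokines and cytokines 0.60 and ABC drug transporters -0.0361.

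With chromosome medians subtracted, fatty acid oxidation had -0.0208 for JC-P over JC-WT. For JC-M3 over JC-P they were phosphagen and adenylate kinases -0.26, epithelial genes -0.83, basal and myoepithelial mammary genes 0.00795 and lung metastasis genes 0.37. For JC-M3 over JC-WT they were respiratory complexes II and III 0.0346, glycolysis -0.28, collagens and matrix 0.56 and stemness and Wnt -0.36.

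Pseudocount 2 gave -0.49 for epithelial genes, JC-M3 over JC-P, and 0.35 for fibroblast markers, JC-P over JC-WT, and pseudocount 0.1 gave 0.73 for the latter. For the pseudocounts and the chromosome medians the cause was not tested.

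The Endothelial markers median log2 ratio, JC-M3 over JC-P, changed sign from -1.40 to 0.0443 with a mean of at least 10 TPM, where Eng was the single marker left.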

Other observations

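The tests on host fibroblasts or muscle and on white blood cells, and the settings with chromosome medians subtracted, were chosen after the results were seen. Matrix-degrading enzymes went both ways. The gelatinase gene Mmp2 stood at 45.6 TPM in JC-WT, 123 TPM in JC-P and 47.9 TPM in JC-M3, while the stromelysin gene Mmp10 stood at 39.7, 32.3 and 3.47 TPM. The tumour necrosis factor gene Tnf stood at 0.84 TPM in JC-P and 10.9 TPM in JC-M3 (log2 3.10, 2.74 to 4.87), and the chemokine gene Ccl5 at 84.8 and 239 TPM. The Wnt antagonist gene Nkd1 stood at 19.2 and 2.97 TPM, and the integrin gene Itgb4 at 54.4, 26.0 and 7.36 TPM across JC-WT, JC-P and JC-M3.

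Few markers of blood cells were measured. The neutrophil gene S100a8 stood at 2.15, 1.32 and 4.41 TPM in JC-WT, JC-P and JC-M3, the lymphocyte gene Il2rb at 5.43, 4.79 and 2.96 TPM and the B cell gene Pax5 at 6.33, 6.88 and 4.73 TPM. No gene of the adipocyte or red blood cell lists reached 1 TPM.

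The 12 genes with the highest ratios of JC-M3 over JC-P were led by the smooth muscle genes Myl9 and Acta2. Host fibroblasts or muscle cells in the JC-M3 culture would bring their other abundant transcripts. Of 11 measured markers of these cells, 4 were at least 2-fold lower in JC-M3 than in JC-P and 2 higher. Col1a2 was 0.00464 of Col1a1 in JC-M3. The markers thus did not rise together from JC-P. However, JC-P itself came from tumours and had a fibroblast marker median of 0.55 over JC-WT. Over JC-WT, the 8 fibroblast markers had a median of 0.95 in JC-M3, with 4 at least 2-fold higher and 1 lower. These markers include matrix genes such as Col1a1, Col3a1 and Dcn, so their medians are not separate from the matrix pattern. The test therefore cannot exclude host cells. Reads shared with related genes are a poor account, since the median share of 50-base windows of the 12 leading genes found in other genes was 0. No biological explanation was tested, and a difference between the populations or between their cultures stays open.

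The interferon-stimulated list had a raised median in JC-P over JC-WT. White blood cells in the JC-P culture would raise their markers, but 0 of 7 measured white blood cell markers were at least 2-fold higher in JC-P, and 42 of 56 had 0 reads there. Chromosome-wide shifts between the libraries leave the pattern in place, with a list median of 0.88 after chromosome medians were subtracted. No biological explanation was tested. In JC-M3 over JC-WT the list was raised as well, with a median of 0.64 and 36 of 40 genes above 0. A passing state of the JC-P culture alone would thus not account for the pattern. Both comparisons share the single JC-WT library, so a state of that culture stays open.

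Genes on chromosome 13 were lower in JC-M3 than in JC-P along the whole chromosome. The linear trend with GC content and length explained 0.475% of the variance among genes, so removing it moved little and left a median of -0.48; a bias of another form stays open. A few strongly changed genes cannot be the whole account, since 87.0% of its 437 genes lay below the median of all genes. The median without genes past 2-fold, -0.46, adds little to this, because that filter selects on the change itself. Loss of a chromosome 13 copy in part or all of the JC-M3 cells may underlie the pattern, as a hypothesis that was not tested, since DNA was not analysed here.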
